A study of Mus musculus with 8 samples.

How the data were processed

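Total RNA (100 ng per array) from 8 mouse samples had been amplified, labelled with biotin and hybridized to Affymetrix mouse expression arrays, per the labels' protocols. The extraction protocol in the labels names hepatocytes, which are not among these samples, so these protocol statements are given as labelled only. The deposited table holds log2 probe set summaries made by the authors, and RMA and Partek are named in the submitters' processing notes without versions, settings or order. Which arrays had been normalized together is not stated. The deposited columns differ in their quantiles, and the 4 episomal columns hold far fewer distinct values than the other 4, so the table had not been brought to 1 common distribution as a whole. The log2 values were used as deposited, without further scaling, and scaled versions were computed as alternatives.

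Samples were grouped from their labels into MEF (1 array), control NSC (1), early episomal iNSC (2), late episomal iNSC (2) and retroviral iNSC (2). Of 45141 probe sets, 104 were array controls, 28898 carried 1 gene symbol, 551 carried several and 15692 were not in the platform annotation table, and only probe sets with 1 symbol were used. Identifiers of 28689 of them matched the RefSeq table, which served for names only and updated 0 symbols. Each of 17097 genes was represented by its probe set with the highest mean. A gene was tested if its highest value on any array exceeded 4.35, the median of all values, which left 12924 genes.

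Differences were tested with limma (version 3.58.1, in R version 4.3.3, with the package data.table, version 1.17.8). The model had 1 mean per group on all 8 arrays, with 3 residual degrees of freedom, and empirical Bayes variances (prior degrees of freedom 4.17, prior SD 0.126). P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of each contrast, with a threshold of 0.05. The MEF and NSC groups add no residual, so their contrasts take the spread from the iNSC replicates. The contrasts were the mean of the 3 iNSC groups against MEF and against NSC, late against early episomal iNSC, the mean of both episomal groups against retroviral iNSC, and each iNSC group against NSC. The NSC and MEF arrays were compared without a test. Their genes differing at least 4-fold were used to score, on each iNSC array, the share of genes nearer to NSC than to MEF.

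Gene lists were fixed before the data were examined and hold genes by general knowledge. They number 25, with 463 genes, of which 414 were on the array and 341 were tested. They cover neural stem cell markers, fibroblast and extracellular matrix, smooth muscle and myofibroblast, the reprogramming factors, pluripotency, neuronal, astrocyte, oligodendrocyte lineage, forebrain, midbrain with hindbrain and spinal cord, Hox, epithelial, cell cycle, p53 and senescence, interferon response, MHC class I, imprinted, cholesterol synthesis, glycolysis and hypoxia, FGF and EGF feedback, microglia and macrophage, endothelial, skeletal muscle, hepatocyte and sex chromosome genes. Each list was tested against all other genes with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a contrast, and again with the correlation estimated from the arrays. A list was called where the preset test had adjusted p below 0.05. Over the 4 main contrasts 31 of 100 list tests were called, and 0 with an estimated correlation. The estimate rests on 3 residual degrees of freedom, so a call lost there cannot tell correlated genes from too few arrays. With single arrays, the median of a list was placed among 10000 random lists of the same size matched on expression.

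Genes were named by a rule fixed before the data were examined. For each main contrast it takes the 8 largest rises and 8 largest falls past the threshold, and from each list up to 4 members with the largest changes, passing over genes with only a clone or locus name. It also takes the 8 largest differences each way between NSC and MEF, and Pou3f4, Sox2, Klf4 and Myc always.

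The scripts were tested on simulated data with the arrays, genes and empirical Bayes variances of the real table, in 20 draws with 200 changed genes of 12924. For late against early iNSC, 31.5%, 98.0% and 100% of genes changed by 0.5, 1 and 2 log2 units were recovered, and for iNSC against MEF 19.0%, 95.9% and 100%. The false share among calls averaged 7.22% (from 2.55% to 10.9%) and 6.41% (from 2.76% to 9.64%), slightly above the nominal 5%. A shifted list was called in 20 of 20 draws in both contrasts, and an unshifted list in 1 of 20 and 0 of 20. Genes were drawn independently of each other, so the draws cannot show how the list test behaves when genes are correlated.

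The alternatives were quantile normalization, centring of each array on its median, other filters, the mean of all probe sets of a gene, a trended and robust variance prior, a replicate block, leaving out each iNSC array in turn, the 6 iNSC arrays as 1 group, only the arrays compared, a 2-fold requirement, and an estimated inter-gene correlation. Fits without the 4 episomal arrays and without the 2 early episomal arrays, and a list of ribosome biogenesis genes, were added after the data were seen. The fit without the 4 episomal arrays has 1 residual degree of freedom, from the 2 retroviral arrays, so its tests rest on that pair alone.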

Results

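Gene expression was measured on 8 single-colour oligonucleotide arrays of mouse cells. Mouse embryonic fibroblasts (MEF, from embryonic day 13.5) and control neural stem cells (NSC, isolated from mouse brain) had 1 array each. Induced neural stem cells (iNSC) had been made from MEF with vectors for Pou3f4 (Brn4), Sox2, Klf4 and Myc. They comprised 2 arrays of early episomal iNSC (passage 5), 2 of late episomal iNSC (passage 20) and 2 of retroviral iNSC (passage 10 in the titles, with passage 11 in the description of replicate 2). Values were log2 signals for 17097 named genes, of which 12924 were bright enough to be tested, and the number of arrays limits the precision. Levels are given as the log2 signal, for groups as mean ± SD (n = 2), and changes as log2 fold change ± standard error (SE). Changes that start or end below 4.35, the level a gene had to exceed on some array to be tested, are read as lower bounds, and their order by size is limited in the same way. Adjusted p-values come from limma (two-sided, Benjamini-Hochberg) and measure only the spread between replicate arrays. The labels call these biological replicates without saying whether they are separate cultures, and the single MEF and NSC arrays are assumed to vary like the iNSC arrays.

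The MEF and NSC arrays set the scale for what follows, and their differences have no replicate check. Olig1 and Olig2, transcription factors of neural progenitors and the oligodendrocyte lineage, read 12.2 and 10.0 in NSC and 3.56 and 3.43 in MEF. Col3a1, a fibrillar collagen, read 3.87 in NSC and 12.3 in MEF. By size, the other leading genes were Aqp4, Aldoc, Phyhipl, Trim9, Gpm6a and Rfx4 on the NSC side and S100a6, Ptgs2, Lyz2, Ccn2, Lgals3, Bgn and Mgp on the MEF side. In all, 361 genes were at least 4-fold higher in NSC and 740 at least 4-fold higher in MEF. Medians of the astrocyte (3.42), neural stem cell marker (2.62) and cholesterol synthesis (2.59) lists were above those of all 10000 random lists of the same size and brightness (percentile 100). Medians of the fibroblast (-4.91), interferon (-3.30), microglia and macrophage (-2.98), imprinted (-2.93), smooth muscle (-2.42) and skeletal muscle (-2.02) lists were below those of all random lists (percentile 0).

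How near each iNSC group came to NSC was read first from those genes. Of the 361 genes higher in NSC, 76.2% ± 0.392 (SD, n = 2) were nearer to NSC than to MEF in early episomal iNSC, 67.04% ± 0.392 in late episomal iNSC and 82.1% ± 0.196 in retroviral iNSC. Of the 740 genes higher in MEF, 84.9% ± 1.34, 90.3% ± 0.0956 and 86.5% ± 0.764 were nearer to NSC in the same groups. The genes were chosen on the same 2 single arrays that define the end points, so the shares carry the noise of those arrays. Across genes, which are not independent replicates, Pearson's r with the NSC array was 0.917 and 0.917 for the early, 0.916 and 0.914 for the late and 0.944 and 0.940 for the retroviral arrays. Their r with the MEF array lay between 0.806 and 0.836, and replicate arrays correlated at 0.991, 0.992 and 0.996.

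The 4 episomal arrays form a technical set of their own. Each held between 3730 and 4013 distinct values, while the MEF, NSC and retroviral arrays held between 40306 and 40934. On the episomal arrays the 3 probe sets for 18S ribosomal RNA averaged 9.18 against 11.5 on the other 4, and the Gapdh probe sets for the 3' and 5' ends, a sign of RNA integrity, differed by 0.898 against 0.199. The retroviral arrays had higher medians (4.66 and 4.65) than the others (4.17 to 4.28). Comparisons that include the episomal arrays carry these differences.

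How iNSC differed from the MEF culture was asked by setting the mean of the 3 iNSC groups against MEF. In iNSC, the oligodendrocyte lineage factor Olig1 rose by 8.34 ± 0.106 (SE, 6 iNSC arrays, 1 MEF array, limma adjusted p = 1.14e-07) and Olig2 by 7.35 ± 0.117. Aldoc, a brain isoform of a glycolytic enzyme, rose by 7.73 ± 0.116. Ptgs2, the inducible cyclooxygenase, fell by 7.66 ± 0.112 (limma adjusted p = 1.25e-07), the lysozyme gene Lyz2 fell by 7.15 ± 0.260, and Ccn2, a matricellular protein of connective tissue, fell by 6.73 ± 0.123. The other leading genes were Trim9, Rfx4, Ncan, Pantr1 and Sox2 among rises and S100a6, Lgals3, Tfpi2, Gask1b and Col3a1 among falls.

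Of 25 neural stem cell markers, 22 rose, 1 fell and 2 were not past the test, with a mean of 3.01 (limma camera, adjusted p = 7.42e-13, and adjusted p = 0.0756 with an estimated correlation). Fabp7, a fatty acid binding protein of radial glia, went from 7.19 in MEF to 12.5 ± 0.0082 in early, 12.5 ± 0.0553 in late and 12.6 ± 0.0269 in retroviral iNSC, beside 12.7 in NSC. All 26 fibroblast and extracellular matrix genes fell, by 4.01 on average (adjusted p = 1.05e-14, and adjusted p = 0.0756 with an estimated correlation). The collagen Col6a3 fell by 5.28 ± 0.113 and the collagen cross-linking enzyme Lox fell by 5.55 ± 0.188. Of 16 cholesterol synthesis genes, 15 rose and 0 fell, with a mean of 1.85 (adjusted p = 9.43e-08, and adjusted p = 0.323 with an estimated correlation). Idi1, an isomerase of the isoprenoid pathway, rose by 3.40 ± 0.241, and Dhcr7, which catalyses the last step to cholesterol, by 2.56 ± 0.243. Per the labels' protocols, MEF were grown with fetal bovine serum and iNSC and NSC in NSC medium with growth factors, so the medium differed with the cell type.

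**Figure D1:**
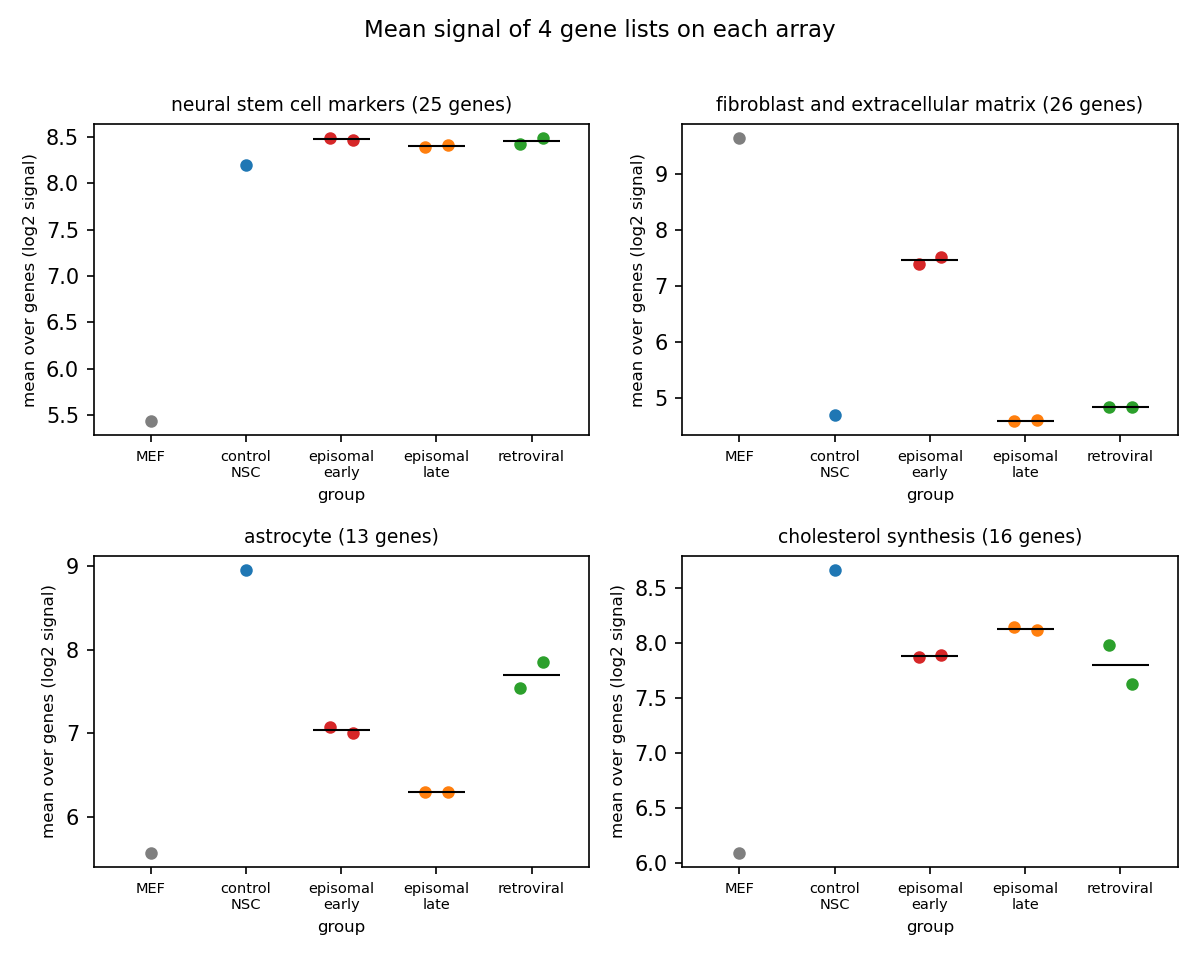
Mean log2 signal (y axis) over the genes of 4 lists on each of the 8 arrays, by group (x axis). Points are arrays and horizontal lines are means of 2 arrays. The fibroblast list read 9.65 on the MEF array, 7.41 and 7.52 on the early episomal arrays and between 4.595 and 4.855 on the late episomal and retroviral arrays, while the neural stem cell marker list read between 8.40 and 8.49 on every iNSC array.

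Lists of other cell types and states also moved. Of 18 interferon response genes 16 fell and 1 rose (mean -3.01, adjusted p = 1.48e-07, and adjusted p = 0.0758 with an estimated correlation). Ifit1, an interferon-induced protein, fell by 4.70 ± 0.144, and Usp18, a deconjugase of the same response, fell by 5.09 ± 0.130. Of 16 imprinted genes 14 fell and 1 rose (mean -3.03, adjusted p = 2.18e-07, and adjusted p = 0.111 with an estimated correlation), among them the growth regulator Grb10, which fell by 6.06 ± 0.146. Of 13 microglia and macrophage genes 12 fell and 0 rose (mean -2.64, adjusted p = 1.61e-05, and adjusted p = 0.111 with an estimated correlation). The complement gene C1qb read 6.81 on the MEF array and between 2.88 and 3.72 in the iNSC group means. Smooth muscle genes fell in 10 of 11 cases (mean -3.20, adjusted p = 9.27e-06, and adjusted p = 0.218 with an estimated correlation), and skeletal muscle genes fell in 11 and rose in 1 of 13 (mean -1.76, adjusted p = 0.000375, and adjusted p = 0.111 with an estimated correlation). The skeletal muscle call ended when genes were filtered on their mean over arrays (limma adjusted p = 0.21). The microglia and macrophage list averaged 6.78 on the MEF array and 3.91 on the NSC array, and the skeletal muscle list 6.14 and 4.45. Other cell types in the MEF culture may therefore contribute to these falls and to that of Lyz2, which was not tested. MHC class I genes fell in 7 of 8 cases (mean -1.56, adjusted p = 0.00646, and adjusted p = 0.323 with an estimated correlation).

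The remaining 3 called lists also depended on the settings. Astrocyte genes rose in 8 and fell in 3 of 13 cases (mean 1.45, adjusted p = 0.0300, and adjusted p = 0.426 with an estimated correlation), with Acsbg1, an acyl-CoA synthetase, up by 4.99 ± 0.131. That call ended after quantile normalization (limma adjusted p = 0.0934), without a filter (0.0676), without the 4 episomal arrays (0.0531) and without the 2 early arrays (0.0859). Epithelial genes fell in 6 of 10 cases (mean -1.08, adjusted p = 0.0462, and adjusted p = 0.269 with an estimated correlation), and this call ended under most alternatives, with limma adjusted p = 0.0627 after centring, 0.127 without a filter, 0.699 with the filter on the mean over arrays, 0.0749 with the mean of probe sets, 0.116 without the 4 episomal arrays and between 0.0502 and 0.060 without any 1 of 5 of the iNSC arrays. All 4 sex chromosome genes fell on average over the 3 groups (mean -1.20, adjusted p = 0.0300, and adjusted p = 0.269 with an estimated correlation). This call ended after centring (limma adjusted p = 0.0501), with the mean of probe sets (0.142), without the 2 early arrays (0.129) and with the 6 iNSC arrays as 1 group (0.766), and without the 4 episomal arrays the relative mean was 0.293 (0.5235). The groups also went apart. Xist, the RNA of the inactive X chromosome, read 10.3 in MEF, 11.03 ± 0.0892 in early and 10.8 ± 0.0413 in late episomal iNSC, and 6.23 ± 0.0554 in retroviral iNSC beside 5.44 in NSC. Eif2s3y, a Y chromosome gene, read 6.90, 3.12 ± 0.0353, 2.68 ± 0.0224, 8.86 ± 0.00175 and 8.37 in the same order.

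The other 13 lists were not called against MEF in the main fit. The cell cycle list was called after quantile normalization (mean 0.40, limma camera adjusted p = 0.0328). The p53 and senescence list was called without the 4 episomal arrays (mean -0.40). Members that rose and fell numbered 10 and 7 of 18 for neuronal genes, 4 and 1 of 11 for the oligodendrocyte lineage, 3 and 1 of 8 for forebrain factors, 5 and 2 of 8 for midbrain, hindbrain and spinal factors, and 8 and 11 of 27 for Hox genes. They numbered 2 and 0 of 6 for pluripotency, 1 and 4 of 6 for endothelial, 2 and 1 of 6 for hepatocyte, 8 and 4 of 25 for cell cycle and 5 and 11 of 18 for p53 and senescence genes. They numbered 6 and 7 of 17 for glycolysis and hypoxia, 2 and 6 of 14 for FGF and EGF feedback, and 2 and 1 of 4 for the reprogramming factors. The neuronal list had a mean of -0.087 and a median of 0.52. Adjusted over the list alone, the counts were the same for every list except imprinted genes, with 15 falling, and glycolysis and hypoxia, with 7 rising.

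Over all genes, 7790 of 12924 passed adjusted p 0.05, 3443 higher and 4347 lower in iNSC. Centring each array on its median moved the all-gene median from -0.034 to -0.19 and the split to 2652 higher and 5121 lower, while quantile normalization moved the median to 0.072 and the split to 3805 higher and 3351 lower. Which side holds more genes therefore depends on the scaling. Within the array sets, retroviral iNSC differed from MEF in 8173 genes and episomal iNSC in 8030, the latter with the array set and the group confounded. Fitted without the 4 episomal arrays, an alternative chosen after the data were seen, 9153 genes passed. For retroviral iNSC against MEF the split depended on the scale of the arrays, with 5428 higher and 2745 lower as deposited, 3520 and 3052 after quantile normalization and 2493 and 4551 after centring. With the 6 iNSC arrays as 1 group, where the differences between iNSC groups count as spread, 1513 genes passed, 566 higher and 947 lower.

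What set iNSC apart from brain-derived NSC was asked with the same mean of the 3 iNSC groups. Sparcl1, a secreted glycoprotein of astrocytes, was 6.70 ± 0.135 log2 units below NSC (SE, 6 iNSC arrays, 1 NSC array, log2 fold change -6.70, limma adjusted p = 2.92e-06). Bex1, a small brain-expressed adaptor, fell by 5.96 ± 0.141, the retinaldehyde dehydrogenase Aldh1a1 fell by 5.37 ± 0.213, the water channel Aqp4 fell by 5.06 ± 0.256 and Efnb2, a ligand of Eph receptors, fell by 4.93 ± 0.136. Above NSC were Tenm3, a cell adhesion protein of the teneurin family, by 5.06 ± 0.112 (limma adjusted p = 2.92e-06), Nrarp, a regulator of Notch signalling, by 3.27 ± 0.161, and Gli2, a transcription factor of hedgehog signalling, by 3.23 ± 0.141. On the MEF array Tenm3 read 9.27, Gli2 7.53 and Nrarp 4.46, beside 3.14, 4.10 and 5.19 in NSC. Tenm3 (7.72 to 9.04) and Gli2 (7.03 to 7.56) thus lay nearer to MEF than to NSC on every iNSC array. Ramp1, Zfp711 and Nebl were among the 8 largest falls, and Xist, Rps6ka6, B3gat1, Car3 and Anks1b among the 8 largest rises. Rps6ka6 and Car3 read 7.46 and 6.59 in MEF beside 4.15 and 3.80 in NSC. B3gat1 and Anks1b were low in both (3.94 and 3.26 in MEF, 4.12 and 2.76 in NSC). The Xist rise came from the episomal arrays (10.8 to 11.1), with 6.19 and 6.27 on the retroviral arrays beside 5.44 in NSC.

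Of 13 astrocyte genes, 9 fell and 1 rose (mean -1.95, camera adjusted p = 1.52e-05, and adjusted p = 0.683 with an estimated correlation), or 10 and 1 adjusted over the list alone. Clu, a secreted chaperone, read 10.3 in NSC, 6.31 ± 0.0650 in early, 4.80 ± 0.383 in late and 5.67 ± 0.783 in retroviral iNSC. Of 16 cholesterol synthesis genes, 11 fell and 0 rose (mean -0.73, adjusted p = 0.000242, and adjusted p = 0.683 with an estimated correlation), or 12 adjusted over the list alone. Lss, the enzyme that closes the sterol ring, fell by 1.71 ± 0.211, and Fdps, which makes farnesyl diphosphate, fell by 1.24 ± 0.166. Of 25 neural stem cell markers, 8 rose, 3 fell and 14 were not past the test (mean 0.25, median -0.023, limma adjusted p = 0.672). Sox21 rose by 1.93 ± 0.108 and Sox11 by 1.75 ± 0.116, both transcription factors of neural progenitors.

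Of 26 fibroblast and extracellular matrix genes, 19 rose and 2 fell against NSC (mean 0.93, adjusted p = 1.52e-05, and adjusted p = 0.599 with an estimated correlation), with 3 falling adjusted over the list alone. Single members went either way in retroviral iNSC. Fstl1 read 10.3 and 10.4 there, beside 7.17 in NSC and 11.4 in MEF. Fn1 read 6.37 and 6.65, beside 10.2 in NSC and 11.5 in MEF. The excess of the list mean came from the early episomal arrays. Without them, an alternative chosen after the data were seen, the mean was 0.021 (limma adjusted p = 0.990), and without all 4 episomal arrays it was 0.15, which lies 0.22 below the all-gene median of that fit (value -0.22, adjusted p = 0.464). Glycolysis and hypoxia genes rose in 9 and fell in 1 of 17 cases (mean 0.58) without a call for the list (limma adjusted p = 0.0627, and 0.0148 after quantile normalization). The other 20 lists were not called, with adjusted p between 0.198 and 0.877.

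Against NSC, 5542 genes passed adjusted p 0.05, 3095 higher and 2447 lower in iNSC, and after centring 2515 were higher and 2977 lower. Retroviral iNSC differed from NSC in 6329 genes and episomal iNSC in 6498, the latter with the array set and the group confounded. Without the 4 episomal arrays, 7633 genes passed, with the same limit of 1 residual degree of freedom. The split of retroviral iNSC against NSC, which follows the scale of the arrays, is given below with its scaled values. With the 6 iNSC arrays as 1 group, 85 genes passed, 29 higher and 56 lower.

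Taken group by group against NSC, all-gene medians were shifted by -0.13 in early episomal, -0.11 in late episomal and 0.37 in retroviral iNSC, and quantile normalization moved each to between 0.032 and 0.036. List means here are given relative to those medians. The fibroblast list was 2.89 higher than NSC in early episomal iNSC, with 22 of 26 genes up and 1 down (adjusted p = 6.51e-17, and adjusted p = 0.123 with an estimated correlation). It was 0.0048 in late episomal (limma adjusted p = 0.947) and -0.22 in retroviral iNSC (adjusted p = 0.527). Periostin (Postn), a matrix protein, read 9.81 ± 0.0188 in early, 3.95 ± 0.211 in late and 4.07 ± 0.0454 in retroviral iNSC, beside 4.14 in NSC and 11.2 in MEF. Early episomal iNSC also had higher glycolysis and hypoxia (1.09, adjusted p = 0.000375), smooth muscle (1.43, adjusted p = 0.00613), imprinted (1.21, adjusted p = 0.0181) and microglia and macrophage genes (0.59, adjusted p = 0.0281), with estimated-correlation adjusted p = 0.401 for each. The microglia and macrophage call ended after quantile normalization (limma adjusted p = 0.109). Astrocyte genes were lower in all 3 groups, by -1.79 in early (adjusted p = 0.00149), -2.55 in late (adjusted p = 6.40e-05) and -1.63 in retroviral iNSC (adjusted p = 8.70e-07), with estimated-correlation adjusted p = 0.401, 0.684 and 0.601. Cholesterol synthesis genes were lower in early episomal (-0.65, limma adjusted p = 0.0181, estimated 0.729) and retroviral iNSC (-1.23, adjusted p = 2.60e-12, estimated 0.601). FGF and EGF feedback genes were lower in retroviral iNSC (-0.80, limma adjusted p = 0.000522, estimated 0.601) and cell cycle genes were higher in late episomal iNSC (0.45, adjusted p = 0.0488, estimated 0.803). These groups share the single NSC array, and both episomal groups lie in another array set than NSC (18S probe sets 9.18 against 11.5, Gapdh end difference 0.898 against 0.199). For them the cells and the array set cannot in general be told apart. Xist was higher and the Y chromosome genes were lower in both episomal groups than in NSC, so the sex of the cells may differ too. For the fibroblast list, late episomal iNSC of the same set were at the NSC level (0.0048 against 2.89 in early), which argues against the array set as the source of the early excess. The astrocyte list was also lower in retroviral iNSC (-1.63), outside that set.

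Early episomal iNSC differed from NSC in 6198 genes (2320 higher, 3878 lower), or 2960 higher and 2631 lower after quantile normalization. Late episomal iNSC differed in 6166 genes (2468 higher, 3698 lower), or 3107 higher and 2866 lower after quantile normalization. Retroviral iNSC differed in 6329 genes (5429 higher, 900 lower), but in 3855 after quantile normalization (2054 higher, 1801 lower) and in 3956 after centring (1855 higher, 2101 lower). Without retroviral replicate 2 the deposited values gave 4122 genes.

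What changed with passage was asked by setting late against early episomal iNSC, which lie in the same array set (2 arrays each). The SE of these changes pools the spread of all 3 iNSC pairs, the retroviral pair included. The collagen Col3a1 fell by 7.73 ± 0.160 (SE, n = 2 and 2, limma adjusted p = 5.77e-07), from 10.98 ± 0.133 to 3.24 ± 0.236. The late levels of Col3a1, S100a6 (3.15), Mgp (3.47), Penk (3.63) and Klf4 (3.83) lie below 4.35, so their falls are lower bounds. S100a6, a calcium-binding protein, fell by 6.52 ± 0.104, the calcification inhibitor Mgp fell by 5.95 ± 0.102, and Penk, the precursor of enkephalins, fell by 4.96 ± 0.105. Ube2ql1, a ubiquitin-conjugating enzyme, rose by 2.92 ± 0.108 (limma adjusted p = 6.07e-06), and Dusp4, a phosphatase that limits MAP kinase signalling, by 2.16 ± 0.144. Postn, Aspn, Anxa1 and Bgn completed the 8 largest falls and Rab26os, Ehd4, Spry4, Rrp12, Gpatch4 and Nr1d2 the 8 largest rises.

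Of 26 fibroblast and extracellular matrix genes, 24 fell and 1 rose (mean -2.86, camera adjusted p = 2.15e-25, and adjusted p = 0.0680 with an estimated correlation). Of 11 smooth muscle genes 9 fell and 0 rose (mean -2.10, adjusted p = 2.82e-10, and adjusted p = 0.218 with an estimated correlation), with the actin gene Acta2 falling from 10.4 ± 0.0417 to 6.59 ± 0.240. Of 16 imprinted genes 13 fell and 0 rose (mean -1.76, adjusted p = 1.62e-10, and adjusted p = 0.167 with an estimated correlation). The growth factor Igf2 fell by 4.67 ± 0.137, the long noncoding RNA Meg3 fell by 3.71 ± 0.107 and Cdkn1c, a cell cycle inhibitor, fell by 3.49 ± 0.0995. Of 13 microglia and macrophage genes 5 fell and 0 rose (mean -0.54, adjusted p = 0.00243, and adjusted p = 0.252 with an estimated correlation), with Lyz2 falling by 2.07 ± 0.240. Interferon genes fell in 6 and rose in 1 of 18 cases (mean -0.22, adjusted p = 0.0201, and adjusted p = 0.311 with an estimated correlation), but had adjusted p = 0.123 after quantile normalization.

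Of 17 glycolysis and hypoxia genes 8 fell and 0 rose (mean -0.83, adjusted p = 3.91e-05, and adjusted p = 0.433 with an estimated correlation). Pdk1, a kinase that holds back pyruvate oxidation, fell by 4.05 ± 0.131, the mitophagy receptor Bnip3 fell by 2.72 ± 0.181, and the angiogenic factor Vegfa fell by 1.75 ± 0.141. Of 13 astrocyte genes 7 fell and 1 rose (mean -0.74, adjusted p = 0.00330, and adjusted p = 0.487 with an estimated correlation), and Aqp4 fell by 3.15 ± 0.237. FGF and EGF feedback genes rose in 11 and fell in 2 of 14 cases (mean 0.51, adjusted p = 0.00587, and adjusted p = 0.487 with an estimated correlation). The feedback inhibitors Spry4 and Dusp6 rose by 2.02 ± 0.370 and 1.78 ± 0.265, while Fos, an immediate early gene, fell by 3.28 ± 0.105. For Spry4 the retroviral pair, which enters the SE, lay further apart (6.54 and 5.20) than the early (7.82 and 7.98) and late pairs (9.93 and 9.92). Cell cycle genes rose in 13 and fell in 0 of 25 cases (mean 0.49, adjusted p = 2.78e-05, and adjusted p = 0.487 with an estimated correlation), among them the cyclin Ccnd1 by 1.32 ± 0.258.

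Of the genes encoded by the vectors, Klf4 fell by 3.28 ± 0.123 (limma adjusted p = 6.27e-06) and Myc rose by 1.17 ± 0.176 (adjusted p = 0.00502). Sox2 (-0.29 ± 0.116, limma adjusted p = 0.104) and Pou3f4 (-0.23 ± 0.199, adjusted p = 0.434) were not past the test. Neural stem cell markers were not called as a list (4 rose and 4 fell of 25, mean -0.073, limma adjusted p = 0.341), and their means were 8.48 and 8.46 on the early and 8.40 and 8.41 on the late arrays. The other 15 lists were not called, with adjusted p between 0.0531 and 0.979. Adjusted over the list alone, cell cycle genes rose in 19 cases, fibroblast genes fell in 25, microglia and macrophage genes fell in 7, astrocyte genes rose in 2 and fell in 8, glycolysis and hypoxia genes rose in 1 and fell in 9, and 1 imprinted gene rose, with the other called lists as above.

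**Figure D2:**
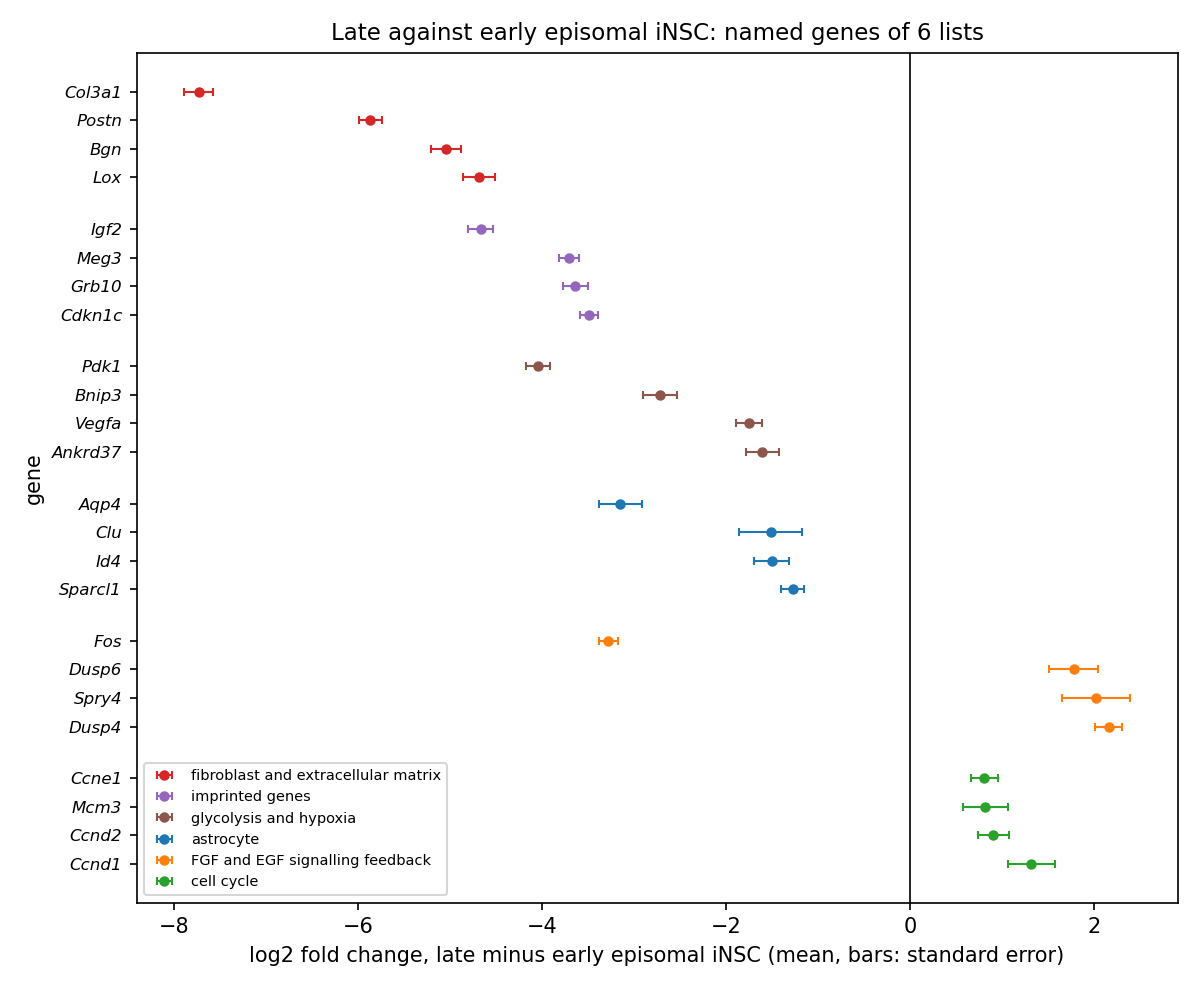
Log2 fold change between late and early episomal iNSC (x axis, 2 arrays per group) for the named genes of 6 lists (y axis). Points are fitted differences and bars are standard errors. The fibroblast, imprinted, glycolysis and astrocyte genes shown lie below 0, from -7.73 for Col3a1 to -1.28 for Sparcl1, and the cell cycle genes and the feedback genes other than Fos lie above 0.

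In all, 3308 genes passed adjusted p 0.05, 1766 higher and 1542 lower in late cells. After quantile normalization 1498 were higher and 1670 lower, and after centring 2114 and 1351, so which side holds more genes depends on the scaling. Leaving out early replicate 1 left 1456, without late replicate 1 there were 2131 and without late replicate 2 there were 1924. Without early replicate 1, Spry4, Ccnd1 and Clu (-1.51 ± 0.340) were no longer past the test, nor was Clu without early replicate 2 or late replicate 2.

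How episomal and retroviral iNSC differ cannot be read apart from the array set, since all 4 episomal arrays lie in the set described above and both retroviral arrays outside it, and the passages differ too. The median gene was 0.50 lower in episomal iNSC (-0.50), and changes here are relative to that median. Mycn, a relative of Myc, was lower in episomal iNSC (-6.198 ± 0.160 SE, n = 4 and 2, limma adjusted p = 6.51e-07 for the unshifted difference), at 11.4 ± 0.325 in retroviral, 4.74 ± 0.263 in early and 4.66 ± 0.0713 in late episomal iNSC. It read 5.21 in NSC and 4.34 in MEF. Sbk1, a protein kinase, had a value of -6.45, and Ackr3, a scavenging receptor for chemokines, of -5.82. Ednrb, the endothelin receptor of neural crest and glia, was 5.39 higher in episomal iNSC (limma adjusted p = 4.52e-07), with 4.59 ± 0.0107 in retroviral cells beside 11.7 in NSC, and the glutamate receptor subunit Grik3 was 5.01 higher. The other leading genes were Xist, Rprm, Ttpa, Matn2, Pdpn and Nap1l5 on the episomal side and Eif2s3y, Hoxa10, Ptgr1, Tmem35a and Zfp947 on the retroviral side.

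Fibroblast and extracellular matrix genes rose in 19 and fell in 2 of 26 cases (relative mean 1.68, camera adjusted p = 3.95e-22, and adjusted p = 0.0833 with an estimated correlation), an average over early cells with high and late cells with low values. Relative means were also above 0 for smooth muscle (0.71, limma adjusted p = 0.000333), cholesterol synthesis (0.70, adjusted p = 8.73e-05), FGF and EGF feedback (0.62, adjusted p = 0.00255), cell cycle (0.57, adjusted p = 0.00370), neural stem cell markers (0.48, adjusted p = 0.0224) and imprinted genes (0.47, adjusted p = 0.0256). With an estimated correlation, limma gave adjusted p = 0.595 for cell cycle and 0.473 for the other 5. The smooth muscle and imprinted values, too, average unlike groups. The smooth muscle list read 7.09 and 7.06 on the early, 4.97 and 4.97 on the late and 5.73 and 5.87 on the retroviral arrays, and the imprinted list 6.77 and 6.80, 5.01 and 5.05, and 5.90 and 5.97. Before the shift, the means of the marker and imprinted lists were -0.018 and -0.029. Members past the test before the shift, up and down, were 6 and 4 of 11, 7 and 4 of 16, 6 and 4 of 14, 5 and 8 of 25, 7 and 10 of 25, and 6 and 7 of 16, in that order. The regional factors Pax6 and Lhx2 were 2.71 and 2.69 higher in episomal iNSC, and the Notch ligand Dll1 had a value of -0.48. The imprinted call ended after quantile normalization (limma adjusted p = 0.123) and after centring (adjusted p = 0.0959). The marker, smooth muscle and feedback calls ended after centring (limma adjusted p = 0.053 for the first pair and 0.0651 for the last). The marker and imprinted calls also ended without retroviral replicate 1, and the cell cycle call without retroviral replicate 2. The other 18 lists were not called, the lowest adjusted p among them being 0.204 by limma.

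Genes encoded by the vectors differed as well. Sox2 was 1.40 and Myc 1.39 higher in episomal iNSC, and Klf4 had a value of -1.31. Myc read 8.003 ± 0.378 in early and 9.17 ± 0.0310 in late episomal iNSC beside 7.70 ± 0.108 in retroviral iNSC, so its value, too, averages unlike groups. The Klf4 value averages unlike groups, with 7.11 ± 0.0986 in early and 3.83 ± 0.0323 in late episomal iNSC beside 7.27 ± 0.178 in retroviral iNSC. Pou3f4 is read by 2 probe sets. The brighter, used for the gene, read 9.51 ± 0.453 in retroviral iNSC, 8.19 ± 0.0939 and 7.97 ± 0.0711 in early and late episomal iNSC, 8.14 in NSC and 4.24 in MEF. The other read 4.08 ± 0.000431, 7.46 ± 0.138, 7.29 ± 0.0818, 7.09 and 3.41 in the same order. The direction of Pou3f4 between the vectors therefore depends on the probe set, with -1.43 for the brighter and 0.93 for the mean of both, each before the shift. Where these probes lie on the transcript is not given, and array signal does not separate vector RNA from endogenous RNA.

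**Figure D3:**
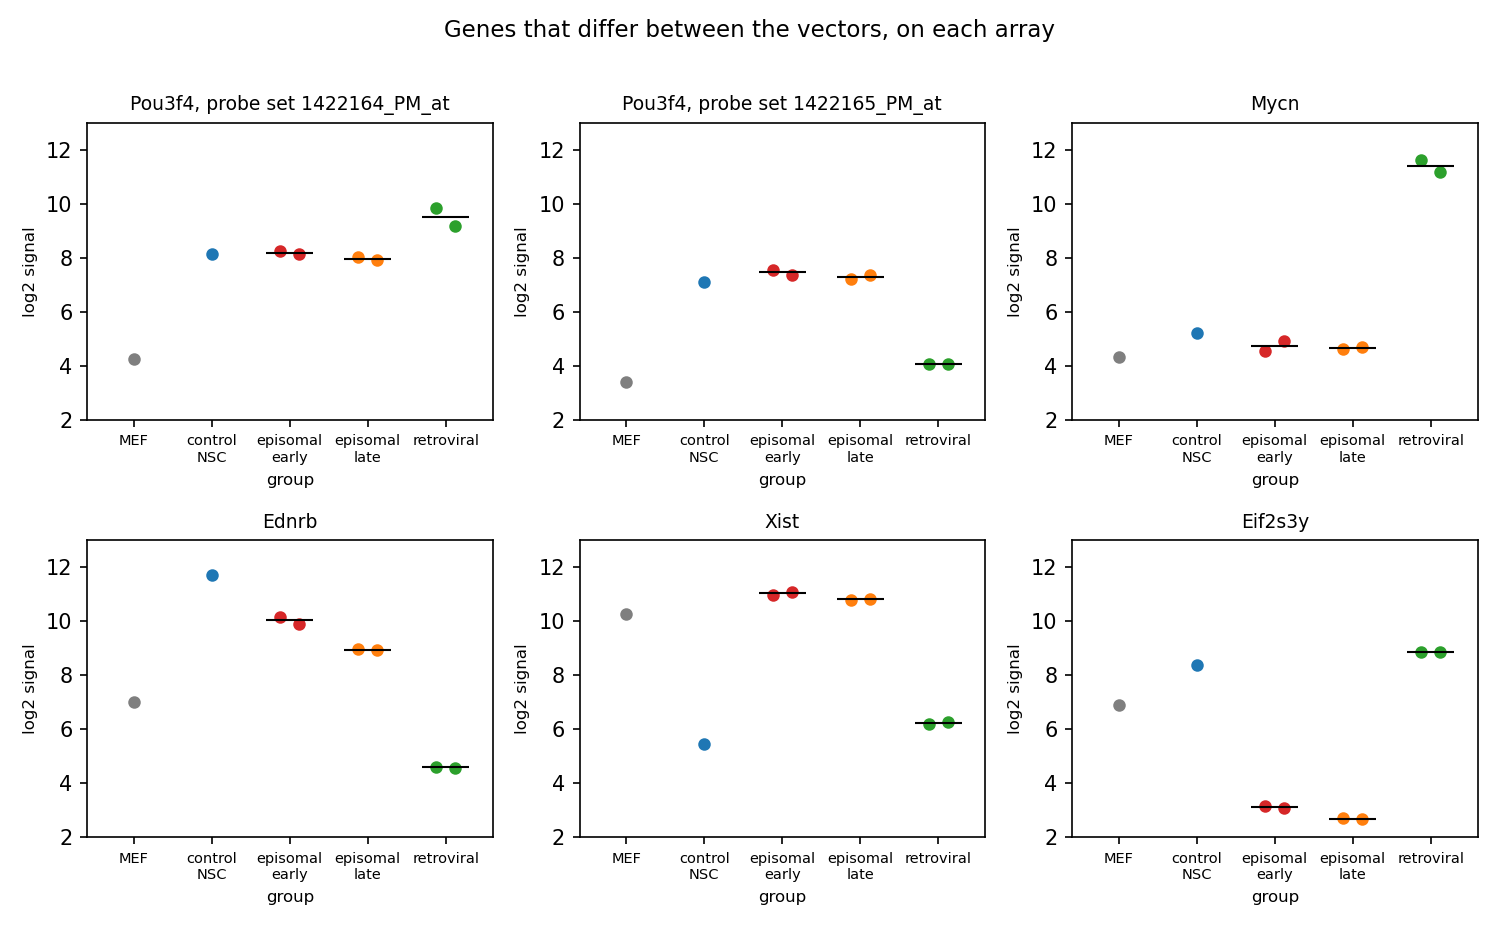
Log2 signal (y axis) of both Pou3f4 probe sets and of Mycn, Ednrb, Xist and Eif2s3y on each of the 8 arrays, by group (x axis). Points are arrays and horizontal lines are means of 2 arrays. Retroviral arrays stand apart for Mycn (11.4) and Ednrb (4.59), the second Pou3f4 probe set reads 4.08 there, and Xist and Eif2s3y are opposite between episomal and retroviral arrays.

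In all, 9515 genes passed adjusted p 0.05, 1221 higher and 8294 lower in episomal iNSC. After quantile normalization 6784 passed, 3346 higher and 3438 lower, and after centring 3172 were higher and 3728 lower. No array set holds both vectors, so no value within a set can be given, and the vector and the array set cannot be told apart. Sex chromosome genes split with the vector as well. Xist read between 10.8 and 11.1 on the episomal arrays and 6.19 and 6.27 on the retroviral arrays. The Y chromosome genes Eif2s3y, Uty and Kdm5d read between 2.67 and 3.49 on the episomal and between 7.39 and 8.86 on the retroviral arrays. The sex of the cells therefore appears to differ between the vectors too, and cannot be told apart from them. The NSC array, with Xist at 5.44 and Eif2s3y at 8.37, read like the retroviral arrays. Comparisons of episomal iNSC, or of the mean of the 3 groups, with NSC therefore carry this difference too. The MEF array held both signals (10.3 and 6.90), so comparisons with MEF may carry it as well.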

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

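All technical tests in this part were chosen after the results they weigh had been seen, and no threshold of theirs was fixed before the data were examined.

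The fibroblast and extracellular matrix list was singled out because late and early episomal iNSC differed in it (-2.89 relative to the all-gene median, limma camera adjusted p = 2.15e-25, but 0.0680 with an estimated correlation). Residual unconverted fibroblasts with the expression of the MEF array would leave a like share of MEF signal for every gene. Over 49 genes high in MEF and low elsewhere, however, the share on the early arrays had a median of 7.13%. Its 90th percentile (27.7%) was 22.72 times its 10th (1.22%), or 23.7 times over 38 genes after quantile normalization. This argues against uniform mixing, although compression of dim signals could widen that range and fibroblasts altered by the NSC medium stay possible. The 49 genes include the macrophage gene Lyz2 (1.29%), so other cell types in the MEF culture could widen it too. Dilution alone, of neural cells that are the same at both passages, would raise neural genes by 0.107 with passage. Instead, 81 of them had a median change of -0.1239 (95% bootstrap interval -0.199 to -0.0254). The interval is over genes, which are not independent, and does not cover the spread between arrays. Astrocyte genes fell with passage, so neural cells that changed could hide a dilution, which that test cannot exclude. The first version of that test used Col3a1 alone, with a required rise of 0.717, and was replaced after its result was seen, with the same outcome, and the numbers of distinct values of late and early arrays had a ratio of 1.047, so value resolution is an unlikely cause.

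Episomal and retroviral iNSC differed in so many genes that the array set was weighed as a cause. Of 1410 genes past the threshold and 2-fold after quantile normalization, 752 (53.33%, interval 50.7 to 56.0) had the 4 episomal arrays on 1 side of the other 4, and 758 (53.8%) had the retroviral arrays apart from the other 6. The array set and the vector cannot be told apart from this share. Its interval is over genes, which are not independent, and does not cover the spread between arrays. The scale of the retroviral arrays alone is an unlikely cause of the number of genes, since 71.3% as many passed after quantile normalization. The excess of lower genes did go with the scale, as the split moved from 1221 higher and 8294 lower to 3346 and 3438. These are totals, which do not show how many of the same genes passed both times.

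The second Pou3f4 probe set was singled out as a signal that the gene-level values leave out, since its highest iNSC group mean stood 4.06 above MEF. In retroviral iNSC this probe set read 4.08, below the 4.35 a gene had to exceed to be tested, so its gap to the other, 4.387 larger than in NSC, is read as a lower bound, and a single endogenous transcript read by both is unlikely. Vector RNA read by 1 probe set only might give such a gap. For Klf4, the other factor that could be tested, the gap differed from MEF by -0.8647 (1.27 in retroviral iNSC, 2.14 in MEF and 0.826 in NSC). Its direction depends on whether MEF or NSC is the reference, and where the probes lie is not given. Klf4 therefore cannot decide this.

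The other values here were singled out because the groups differed in a list, and are means relative to the all-gene median. With an estimated correlation none of them was past the limma camera test (adjusted p from 0.0833 to 0.595), and the interferon call and the imprinted call for episomal against retroviral iNSC also ended after quantile normalization (0.123 each). For late against early episomal iNSC they were -2.13 for smooth muscle, -1.79 for imprinted, -0.858 for glycolysis and hypoxia, -0.766 for astrocyte, -0.570 for microglia and macrophage and -0.244 for interferon genes, and 0.487 for FGF and EGF feedback and 0.459 for cell cycle genes. For episomal against retroviral iNSC they were 1.68 for fibroblast, 0.715 for smooth muscle, 0.701 for cholesterol synthesis, 0.620 for FGF and EGF feedback, 0.570 for cell cycle, 0.478 for neural stem cell marker and 0.467 for imprinted genes.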

How the results depend on the processing

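The fits without the 4 episomal arrays and without the 2 early episomal arrays were chosen after the data were seen, and all other alternatives were set before the data were examined and all were run. Counting each result under each alternative in which it was fitted, 415 were weaker, 38 stronger, 26 reversed and 26 moved. The other lists and named genes kept their side of the threshold, with the same direction where they were called. The losses were uneven. With the 6 iNSC arrays as 1 group, 122 named-gene results were weaker and 90 the same. With an estimated correlation, 31 list results were weaker and 69 the same. Genes that an alternative filtered out are not counted there, so the filter on the mean over arrays covered 363 of 417 named-gene results. Counts of genes were compared by their totals only. The side that held more genes changed under at least 1 alternative in every comparison except episomal against retroviral iNSC, whose excess of lower genes nearly vanished after quantile normalization. A 2-fold requirement, which by construction passes fewer genes, left 3041 genes for iNSC against MEF, 1224 against NSC, 545 for late against early, 2376 for episomal against retroviral, and 1943, 2105 and 1751 for early, late and retroviral iNSC against NSC. With the 6 iNSC arrays as 1 group, whose spread then holds the differences between groups, 1513 genes passed against MEF and 85 against NSC. Leaving out 1 array, which by construction lowers precision, gave 1456 to 2548 genes for late against early, 4122 to 6578 for retroviral iNSC against NSC, 6990 to 7916 for iNSC against MEF and 4571 to 5579 against NSC. Except for late against early, the highest of these counts lay above that of the main fit, so the ranges do not show a loss of precision alone. Retroviral iNSC against NSC gave 3855 genes after quantile normalization and 3956 after centring, and 0 lists were called with an estimated correlation. The mean share of genes nearer to NSC was 75.1% for genes higher in NSC, and 76.8% after quantile normalization, 74.8% with the mean of probe sets, 66.9% for 2-fold and 80.0% for 8-fold genes. For genes higher in MEF it was 87.2%, and 89.3% with the mean of probe sets, 77.9% for 2-fold and 88.6% for 8-fold genes. Without a filter, mean r with NSC was 0.948 and with MEF 0.880, and with the mean of probe sets r with MEF was 0.814. The cause was not tested for the changes after scaling, filtering or averaging.

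Some values changed sign. Without the 4 episomal arrays, the sex chromosome list against MEF was 0.293 and the fibroblast list against NSC -0.222, and against MEF Kdm5d was 2.57, Eif2s3y 1.95, Uty 1.87 and Hoxa10 1.24. In that fit against NSC, Uty was 1.35, Gbp2 1.15, Kdm5d 1.10, Btg2 0.974, Eif2s3y 0.482, Fgf4 0.441, Trf 0.350, Ndn 0.240, Irx3 0.224, Myod1 0.0925, Egfl7 0.0212, Eng 0.0164, Postn -0.0687 and Pax3 -0.794. Without the 2 early arrays, Kdm5d against MEF was 0.0586, and Col3a1 and Postn against NSC were -0.0585 and -0.132. With the mean of all probe sets, Tyms was 0.0868 against MEF and 0.0943 against NSC, and Pou3f4 0.931 for episomal against retroviral iNSC. The cause was not tested for these.

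With a replicate block, 7613 genes passed against MEF, 5260 against NSC, 2893 for late against early and 9463 for episomal against retroviral iNSC, and 33 lists were called. Differences between same-numbered replicates correlated at 0.034 for early and late, -0.127 for early and retroviral and 0.051 for late and retroviral iNSC, so the numbers were not taken to pair the arrays. No detection calls were used, so signal near background limits how far low values and small changes of dim genes can be read.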

Other observations

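The ribosome biogenesis list below was chosen after Rrp12, Gpatch4 and Ddx21 had been seen to rise and does not contain them, and its test was written before its values were seen.

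Most single genes of ribosome biogenesis rose with passage in episomal iNSC, while the list as a whole was not past the test with an estimated correlation (limma camera adjusted p = 0.368). Ppan, a factor of large subunit assembly, rose by 1.79 ± 0.181 (SE, n = 2 and 2, limma adjusted p = 0.00116), the nucleolar methyltransferase genes Ftsj3 and Nop2 by 1.40 ± 0.166 and 1.39 ± 0.223, and Nolc1, a nucleolar chaperone, by 1.34 ± 0.192. Ppan read 6.03 ± 0.103 in early, 7.82 ± 0.00124 in late and 6.44 ± 0.396 in retroviral iNSC, 6.19 in NSC and 7.58 in MEF. These 4 genes were chosen after their values were seen.

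The hypothesis was that the class rises as a whole. Of 37 tested members, 34 rose and 0 fell (91.89%), with a mean of 0.93 (SD over genes 0.34) and 0.90 after quantile normalization. The limma camera test gave adjusted p = 2.53e-16 at the preset correlation, and the estimated correlation ended this call. With 3 residual degrees of freedom the estimate also ended every other list call of the main contrasts. This loss therefore cannot tell correlated genes from too few arrays. A rise of the class as a whole still rests on taking its genes as nearly independent. Against MEF, 32 of the members were lower and 1 was higher in iNSC on average (mean -0.89, limma camera adjusted p = 3.21e-06, and adjusted p = 0.361 with an estimated correlation). Against NSC, 10 rose and 3 fell (limma camera adjusted p = 0.213, and adjusted p = 0.775 with an estimated correlation). For episomal against retroviral iNSC, 5 rose and 11 fell as deposited (mean -0.078, and 0.38 after quantile normalization). The all-gene median there was -0.50, so the list lay above other genes. For that shift limma camera gave adjusted p = 0.00400, and adjusted p = 0.589 with an estimated correlation.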
